A study of Mus musculus with 2 samples.

How the data were processed

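Single-cell RNA sequencing was done on cells sorted from adrenals of male SF1-Cre; Rosa mTmG mice, in 2 libraries of 1 group. The deposited values were UMI counts per gene and cell barcode, made by the authors with Cell Ranger on genome build mm10 with eGFP and TdTomato in the reference. Per the file headers the software version was 3.1.0, and how cells were called is not given in the sources used here. Per the labels, 26 adrenals were pooled and live cells positive for a DNA dye were sorted, with no gate on GFP named. The 31057 features include 4 reporter or transgene features. Of all features, 30934 identifiers matched GENCODE vM21 and 123 did not, and 118 of 118 named genes matched. Symbols carried by more than 1 feature numbered 36.

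Cells were kept with at least 1000 UMIs, at least 500 genes and at most 30% mitochondrial UMIs, which removed 148 barcodes of library 1 and 276 of library 2. Doublets were scored with scrublet in scanpy 1.11.5 per library and the highest-scoring cells removed at 0.8% per 1000 barcodes, 203 and 42 cells. Doublets between like cells stay undetected, and free RNA was not subtracted. Kept cells held medians of 18178 and 14809 UMIs. Clustering used a random part of the genes (15231 available, 2000 variable ones used, seed 1), without marker genes, list genes, mitochondrial, ribosomal or reporter genes. Values scaled per library went through a joint PCA (30 components), 15 nearest neighbours and Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) at resolution 0.5, which gave 15 clusters. The other 15731 genes were available to test, so no gene was tested that had shaped the clusters.

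Clusters were named from 91 fixed marker genes in 14 lists. The partition along the zG-like to zF-like range was not stable between early versions of the clustering code. Names were assigned anew each time with marker levels in view, and the ranking of top genes by fold over all other cells was settled after markers had been seen. Clusters without a clear match were left unnamed.

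UMIs were summed per cluster and library over cortical clusters with at least 20 cells in each library, giving 16 sums from 8 clusters. Clusters 4 and 7 had too few cells in 1 library and were left out. One edgeR 4.0.16 quasi-likelihood model (R 4.3.3, limma 3.58.1) with terms for cluster and library was fitted to 5959 genes after its low-count filter, with TMM scaling and 7 residual degrees of freedom between sums. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. They rest on how far cluster differences varied between the 2 libraries, pooled over the 8 clusters. The variance of each gene was also drawn toward that of other genes, with 31.8 prior degrees of freedom beside the 7 residual ones. The standard error of a gene thus need not show how far its own difference varied between the 2 libraries. The library term takes out shifts common to all clusters of a library, and the animals are not listed separately. The biological coefficient of variation was 0.0644. Camera (limma) tested 17 gene lists with a preset correlation, beside an estimated correlation and fry, with adjustment over the lists. Shares have exact Clopper-Pearson 95% intervals, and intervals cover counting error only. Cells counted as cycling had UMIs of at least 3 cell cycle genes after thinning to 5000 UMIs, which left out 616 shallower cells. A group with no UMI was set to a floor of 3 UMIs over the group.

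The filters, gene lists, marker lists, main comparisons and rule for named genes were chosen before the data were examined. In the comparison of zG-like with zF-like cells the rule took genes past the threshold with the same sign in both libraries, at least 20 CPM on the higher side and no gene-model name, the 10 largest changes in each direction. It took 4 in each direction between the zF-like clusters, up to 2 per list and direction, and a few genes fixed by name. Some genes that the rule took are not reported here. Comparisons of cluster 0 with cluster 1, of cycling clusters with zG-like cells and of single zF-like clusters with zG-like cells were added after the data were seen. Marker genes were used only to name clusters. Of the fixed genes, Ccn1, Ccn2 and Ccn3 were not analysed here, as no feature used here carried those symbols. Reads of close paralogs (Cyp11b1 and Cyp11b2, Hsd3b1 and Hsd3b6, Aldh1a1 and Aldh1a7, and the glutathione transferase, metallothionein, histone and haemoglobin families) may be shared, which the counts cannot resolve.

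Alternatives covered RLE size factors, DESeq2 1.42.0, no low-count filter, no library term, thinned cells, resolutions of 0.3 and 1.0, the other gene part, all genes, doublets kept, at most 15% mitochondrial UMIs, at least 1500 genes per cell, class sums and each library alone. Leiden seeds 2 and 3, each zF-like cluster alone and a fit without clusters 3 and 6 were added after the data were seen. The model was tested on simulated data with 5640 genes. It called 78 of 94 genes changed by a log2 of 1 and 98 of 99 changed by a log2 of 2. False calls made up 2.22% of calls. The simulated data held no library effect, no other differences between clusters and few changed genes. These rates need not hold for the real data, where 39.5% of genes were called between zG-like and zF-like cells. Other computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0.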

Results

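Cells sorted from dissociated adrenal glands of male mice aged 15 weeks were profiled with a droplet 3′ RNA kit (version 3.1). The mice carried SF1-Cre, which is active in steroid-producing lineages, and the Rosa mTmG reporter, in which Cre recombination replaces membrane tdTomato with membrane GFP. The 26 adrenals of the study went into 2 libraries with identical labels, so the series holds 1 group with 2 replicates, called library 1 and library 2. How the animals were divided between the libraries is not given in the sources used here. Library 1 held 5040 barcodes and 92905273 UMIs, and library 2 held 2288 barcodes and 28023733 UMIs. After filtering, 4689 and 1970 cells remained, with medians of 18178 and 14809 UMIs per cell. Summed levels of 12165 genes correlated between the libraries across genes (Pearson's r 0.984, Spearman's rho 0.984), although genes are not independent replicates. A chi-square statistic of 142 per degree of freedom showed differences far above counting error, and the libraries shared 4 barcodes.

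With a single group, the comparisons lay between cell states inside the libraries and asked how steroidogenic cells of the male cortex differ from each other. Clusters 0 and 1, of 2318 and 1430 cells, were named zG-like after markers of the zona glomerulosa, the outer aldosterone-producing zone. Clusters 2 and 9, of 1371 and 51 cells, were named zF-like after markers of the zona fasciculata, which makes corticosterone. The name of cluster 2 rested mainly on Cyp11b1, at 947 CPM (UMIs scaled by all UMIs of the cluster's cells, pooled over both libraries) against 124 in cluster 0 and 185 in cluster 1. Cluster 2 also kept zG markers, with Wnt4 at 1643 CPM against 2358 in cluster 0 and Shh at 332 against 263. The zG markers Vsnl1 (146 against 658) and Cyp11b2 (9.99 against 129) were lower there. The zF marker Mrap did not set cluster 2 apart, at 121 CPM against 117 in cluster 0 and 130 in cluster 1. Cluster 9 had more of the zF markers Cyp11b1 (2278 CPM), Abcb1b (8005) and Mrap (412, against 121 in cluster 2) and less Wnt4 (143). It also had more Thrb, from the fixed markers of another cortical zone, the X-zone, at 74.8 CPM against 16.9 in cluster 2. Akr1b7, another zF marker, went against the name, at 108 CPM in cluster 9 against 953 in cluster 2, 1141 in cluster 0 and 1226 in cluster 1. Reads of Cyp11b1 and its close paralog Cyp11b2 may be shared, which leaves both levels uncertain.

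The zG-like class made up 59.4% of kept cells in library 1 (exact 95% interval 58.0 to 60.8) and 48.8% in library 2 (46.6 to 51.1). The zF-like class made up 19.4% (18.3 to 20.6) and 25.9% (24.0 to 27.9). Cluster 1 held 1247 cells of library 1 and 183 of library 2, so the clusters that fill the zG-like class differed between libraries. Unnamed cortical clusters held 19.3% and 21.5% of cells. Among them were clusters 5 and 8, led by cell cycle genes, cluster 3, with medians of 5876 and 4145 UMIs per cell, and cluster 4, with 210 cells in library 1 and 4 in library 2. Cells in clusters led by immune genes made up 1.81% (1.45 to 2.24) and 3.71% (2.92 to 4.64). All of these shares depend on the sort, which kept DNA-dye-positive, DAPI-negative cells, and on the filters. Those of the zG-like and zF-like classes also depended on the clustering. With Leiden seed 2 the zG-like share was 54.5% in library 1 and 46.0% in library 2. The zF-like share was then 24.4% and 28.9%. These values lie outside the intervals above, which cover counting error only, though the order of the libraries was unchanged. No test between groups was possible with 1 group.

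**Figure D1:**
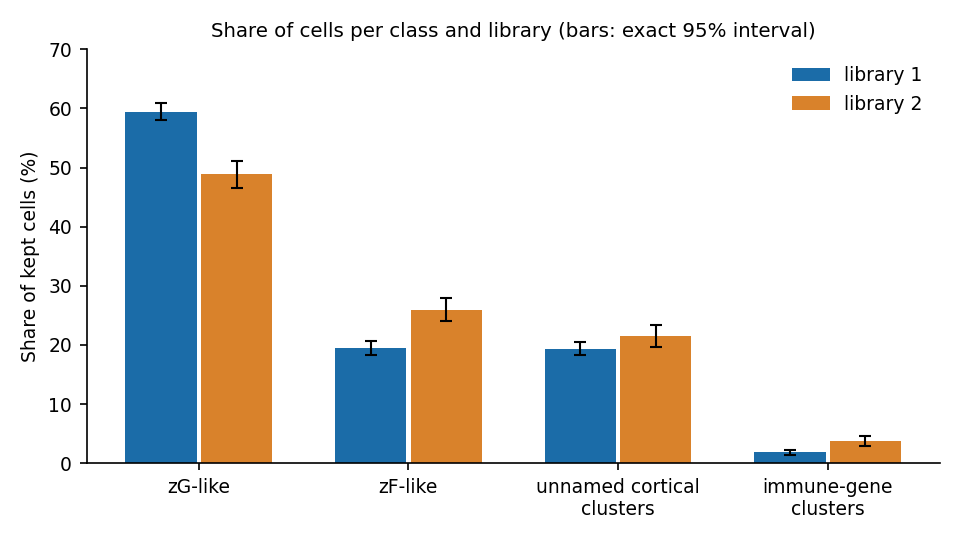
The vertical axis gives the share of kept cells in percent for 4 classes on the horizontal axis, with 1 bar per library and exact 95% intervals as error bars. The zG-like class was the most frequent in both libraries, at 59.4% and 48.8%.

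The reporter was read in all classes. In zG-like cells eGFP stood at 3120 and 3580 CPM in libraries 1 and 2, and in zF-like cells at 1938 and 2110. Lymphocyte-like clusters, which should lack SF1-Cre activity, had 2592 and 2734 CPM of eGFP, but only 35.3 and 29.6 CPM of Star. Cre had no UMI in them, with floors of 17.6 and 17.8 CPM, against 45.3 and 72.0 CPM in zG-like cells. In zF-like cells Cre stood at 50.2 and 51.4 CPM. The feature bGH had 341 and 349 CPM in lymphocyte-like clusters, against 431 and 568 in zG-like cells. Macrophage-like cells had 2441 and 3437 CPM of eGFP, with Star at 430 and 433 CPM. TdTomato had 2 UMIs in all kept cells.

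**Figure D2:**
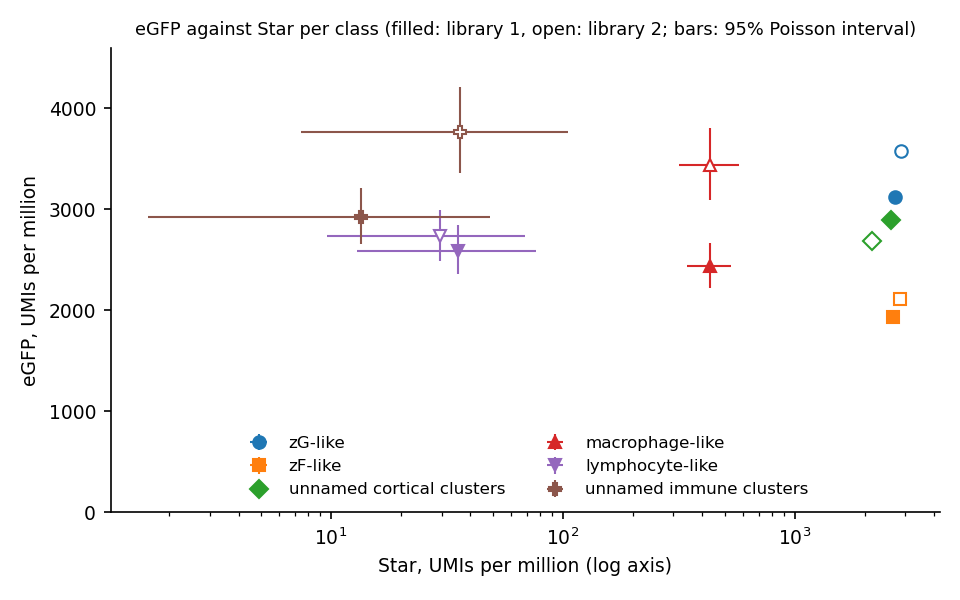
The vertical axis gives eGFP in CPM and the horizontal axis Star in CPM on a log scale, with 1 point per class and library and 95% Poisson intervals as bars. Lymphocyte-like clusters had 2592 and 2734 CPM of eGFP at 35.3 and 29.6 CPM of Star.

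The comparison of zG-like with zF-like cells asked which genes differ between these named classes. It set the mean of clusters 0 and 1 against the mean of clusters 2 and 9, each cluster with equal weight. The 51 cells of cluster 9 thus counted as much as the 1371 cells of cluster 2. Hsd3b1, which encodes the enzyme that converts pregnenolone to progesterone, was lower in zG-like cells (log2 difference -1.06 ± 0.15 SE, n = 2 libraries, edgeR adjusted p 1.46e-07). So was Cyp11a1, the side-chain cleavage enzyme that starts steroid synthesis (-0.40 ± 0.12, edgeR adjusted p 0.00604), a difference that lay with cluster 9 (0.68 ± 0.14 over zG-like cells) and did not pass for cluster 2 (0.12 ± 0.14, edgeR adjusted p 0.556). Star, the carrier of cholesterol into mitochondria, did not pass the test (-0.18 ± 0.13, edgeR adjusted p 0.278). Cyp21a1, the 21-hydroxylase, and Mc2r, the ACTH receptor, were higher in zG-like cells on average (0.77 ± 0.18 and 1.60 ± 0.13). Both of these differences lay with cluster 9, where Cyp21a1 stood at 1523 and Mc2r at 33.5 normalised CPM. In cluster 2 the same genes stood at 5616 and 359, against 4819 and 335 in zG-like cells, and zG-like cells did not differ past the threshold from cluster 2 alone (-0.25 and -0.10, edgeR adjusted p 0.384 and 0.394). The libraries differed in cluster 9, with Cyp21a1 at 2522 in library 1 and 525 in library 2, and Mc2r at 58.1 and 8.93, which gave Mc2r log2 differences of 1.25 and 2.50 in single libraries.

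Genes with the largest rise toward the zF-like state were mostly those of cluster 9. Aldh1a1, a retinaldehyde dehydrogenase, had 0.335 normalised CPM in zG-like cells, 9.99 in cluster 2 and 3693 in cluster 9 (log2 difference -8.94 ± 0.17). Srd5a2, a steroid 5-alpha-reductase, had 0.264, 7.05 and 598 (-7.92 ± 0.22). Aldh1a7 had a single UMI in zG-like cells, and its ratio of cluster 9 over zG-like cells was 13750 (counting interval 2467 to 543000). Ly6a (-6.55), Lgals3 (-6.47), Col5a3 (-5.79), Vegfd (-4.41), Mapk13 (-4.33), Cabp1 (-4.33) and Xdh (-4.27) followed. Single-library values, which are shrunken by a prior count of 2, differed most for Ly6a, at -4.25 in library 1 and -7.50 in library 2. Lgals3 stood at -5.81 and -4.85, Vegfd at -4.29 and -3.55, Xdh at -3.63 and -4.38 and Aldh1a1 at -7.96 and -8.60. Cabp1 was not higher in cluster 2 than in zG-like cells, at 0.333 against 0.411 normalised CPM. The 10 genes with the largest fitted rise toward the zG-like state had no UMI in cluster 9. Against a floor of 3 UMIs over that cluster, the zG-like level was at least 25.1-fold higher for Bex4, 17.0 for Lmo2, 16.9 for Lhfpl2, 11.3 for Fat3 and 11.2 for Fos. It was at least 9.93-fold higher for Tpbgl, 8.42 for Tnc, 8.41 for Tmem51, 7.46 for Cd24a and 6.21 for Nr0b1. With 1 library alone these bounds were lower, between 2.12 for Fos in library 1 and 15.2 for Bex4 in library 1. Fos differed most, at 13.2 normalised CPM in zG-like cells of library 1 and 59.0 in library 2. Of the 10 genes, cluster 2 was also well below zG-like cells in Cd24a (-3.10 ± 0.17), Lmo2 (-1.84 ± 0.15) and Bex4 (-1.20 ± 0.11). Nr0b1, a repressor of SF1, did not differ there past the threshold (0.19 ± 0.12, edgeR adjusted p 0.21).

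Among the other genes fixed to be reported, Nr5a1, the gene of SF1 itself, was higher in zG-like cells on average (0.51 ± 0.10). Over zG-like cells it changed by -0.24 ± 0.09 in cluster 2 (edgeR adjusted p 0.0448) and by -0.78 ± 0.16 in cluster 9. Pooled over cells, Nr5a1 stood at 271 CPM in zG-like against 279 in zF-like cells of library 1. In library 2 it stood at 284 against 236. Axin2, a feedback target of WNT signalling, was also higher in zG-like cells on average (0.85 ± 0.12). It was lower in cluster 9 than in cluster 2, so this average need not hold against cluster 2. Gli1 had 31 UMIs in all sums and was not tested. In genome build mm10, Hsd3b1 (ENSMUSG00000027871) lies on chromosome 3 from 98852194 to 98859794, Cyp21a1 (ENSMUSG00000024365) on chromosome 17 from 34801348 to 34804561, and Mc2r (ENSMUSG00000045569) on chromosome 18 from 68406907 to 68429320. Aldh1a1 (ENSMUSG00000053279, 20492715 to 20643465) and Aldh1a7 (ENSMUSG00000024747, 20692953 to 20727562) are neighbouring paralogs on chromosome 19, so reads may be split between them.

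Over 5959 genes, edgeR's quasi-likelihood test called 1425 genes higher and 930 lower in zG-like cells, of which 409 and 363 changed at least 2-fold. With RLE size factors the split was 1121 higher and 1099 lower. For 2341 of the 2355 called genes the sign was the same in both libraries. Both libraries entered the clustering and the fit, so the calling itself favours such agreement. Cluster 2 alone differed from zG-like cells by at least 2-fold in 178 genes upward and 151 downward, and cluster 9 alone in 551 and 612. Of the 1425 genes, 630 were called the same way against each zF-like cluster alone. Another 269 were so called only against cluster 2, 454 only against cluster 9 and 72 against neither. Of the 930, 110 were called lower only against cluster 2, 380 only against cluster 9 and 48 against neither. Against cluster 2 alone, 29 of the 1425 and 24 of the 930 were called the opposite way. The adjusted p-values measure how cluster differences varied between 2 libraries, with the variance of each gene drawn toward that of other genes. They do not measure the spread between libraries or animals, since a library term was fitted. A gene can have a small standard error although its single-library values differ widely. Of the genes called higher in zG-like cells, 98 had no UMI in cluster 9. Without the library term 1237 genes were called, and with cells thinned to 5000 UMIs 1247.

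**Figure D3:**
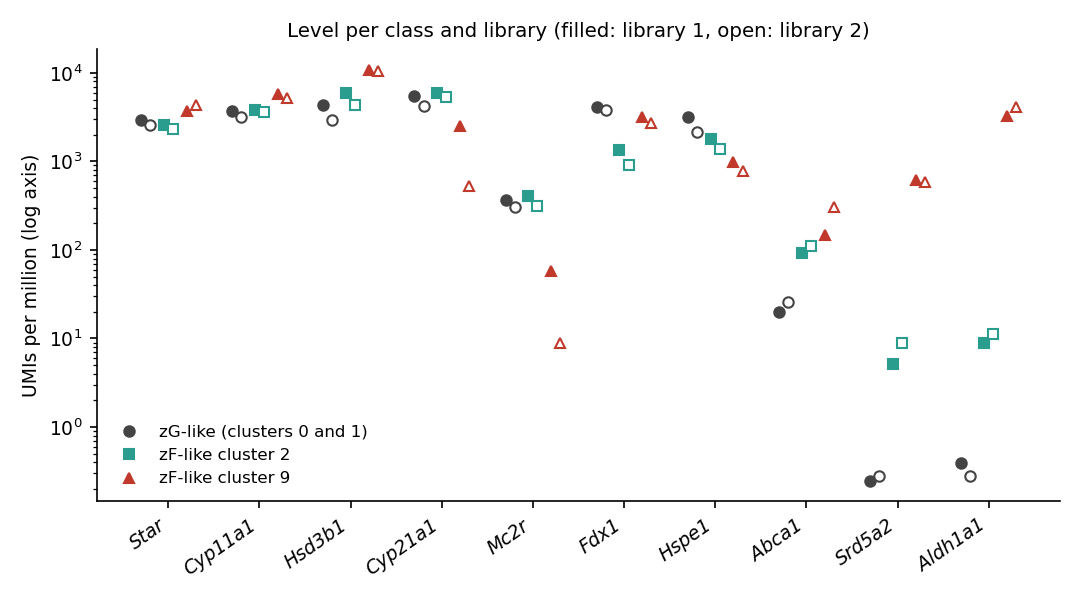
The vertical axis gives normalised CPM on a log scale for 10 genes on the horizontal axis, with 1 point per class and library. Mean Star levels lay between 2431 and 3997, while Aldh1a1 rose from 0.335 in zG-like cells to 3693 in cluster 9.

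Genes of cholesterol synthesis and of oxidative phosphorylation were mostly higher in zG-like cells. Of 24 cholesterol synthesis genes, 17 were higher, 1 lower and 6 did not pass. Hsd17b7 was up (1.70 ± 0.27) and Scap, a sensor of sterol levels, down (-0.75 ± 0.14). Against cluster 2 alone no gene of this list was called lower, so Scap did not pass as lower there. Mvd had 2 UMIs in cluster 9, and its zG-like level was 5.30 times that of cluster 9 (counting interval 1.47 to 43.7). Camera gave an adjusted p of 0.00249 for the list, and adjusted p = 0.439 with an estimated correlation. Nuclear-encoded oxidative phosphorylation showed 28 of 42 genes higher and 1 lower, among them Ndufb5 (0.61 ± 0.09) upward and Sdhb (-0.46 ± 0.08) downward. Its camera adjusted p was 0.000753, and adjusted p = 0.328 with an estimated correlation. Of 13 mitochondrial-encoded genes, 7 were higher, none lower and 6 did not pass, with higher levels of genes such as mt-Co1 (0.68 ± 0.16) and mt-Atp6 (0.55 ± 0.18). Here camera gave 0.0279, and adjusted p = 0.672 with an estimated correlation. Ribosomal protein genes moved little, with 15 of 48 higher, 1 lower and 32 not passed, including Rps24 (0.45 ± 0.12), Rpl15 (0.45 ± 0.10) and Rplp0 (-0.30 ± 0.10). Their camera adjusted p was 0.0249, and adjusted p = 0.689 with an estimated correlation, and the call was lost with RLE size factors (0.0889) and without the library term (0.364). Without that term the oxidative phosphorylation call was lost too (0.0527).

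Against cluster 9 alone, none of these 4 lists passed camera. Cholesterol synthesis kept the size of its difference, with 14 of 24 genes higher and 2 lower (median 0.88, camera adjusted p 0.126), against 20 higher and none lower against cluster 2 (median 0.82). Oxidative phosphorylation had 15 of 42 higher and 2 lower (median 0.23, camera adjusted p 0.228), against 38 and none for cluster 2 (median 0.37). Mitochondrial-encoded genes had 1 of 13 higher (0.601) and ribosomal proteins 6 of 48 higher and 2 lower (0.905). The nuclear RNA Malat1, named after its values were seen, was lower in zG-like cells (-0.83 ± 0.24, edgeR adjusted p 0.00531), at 22010 normalised CPM against 37380 in cluster 2 and 39650 in cluster 9.

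Lists of signalling genes tied to the outer cortex were higher in zG-like cells on average over both zF-like clusters, but did not pass against cluster 2, the larger one. In the angiotensin, potassium and calcium list, 18 of 34 genes were higher and 4 lower. The potassium channel Kcnk9 (2.17 ± 0.15) and Rgs4 (2.58 ± 0.19), which dampens receptor signalling, were higher, and Clcn2 (-1.43 ± 0.22) and Plcb4 (-1.28 ± 0.14) lower. In cluster 9 the libraries differed, with Kcnk9 at 64.3 and 6.70 normalised CPM and Rgs4 at 22.8 and 0, and their log2 differences were 1.62 and 1.88 in library 1 alone and 3.50 and 5.50 in library 2 alone. Camera gave 0.0249, and adjusted p = 0.257 with an estimated correlation. Of 28 WNT pathway genes, 15 were higher and 7 lower. Sfrp1 had no UMI in cluster 9 and was at least 2.95-fold higher in zG-like cells (at least 1.12-fold and 1.80-fold with library 1 or 2 alone). Apcdd1, with no UMI there either, lay below the floor of each library, while Wnt5a (-1.69 ± 0.16) and Fzd1 (-1.47 ± 0.35) were lower. The camera adjusted p was 0.0279, and adjusted p = 0.328 with an estimated correlation. Among 18 hedgehog and FGF genes, 10 were higher and 3 lower. Spry4 had no UMI in cluster 9 and lay near the floor in zG-like cells, Etv4 lay below it, and Fgfr1 (-0.76 ± 0.13) and Gas1 (-0.69 ± 0.11) were lower. Camera gave 0.0249, and adjusted p = 0.257 with an estimated correlation, and the list's median of 0.80 fell to 0.50 with the unseen genes at the floor. Against cluster 2 alone, 11 of 34 angiotensin list genes were higher and 7 lower (camera adjusted p 0.526), 10 of 28 WNT genes higher and 5 lower (0.407), and 5 of 18 hedgehog and FGF genes higher and 5 lower (0.624, median -0.09). Against cluster 9 alone the adjusted p-values were 0.0327, 0.0617 and 0.0127, and adjusted p = 0.167, 0.271 and 0.167 with an estimated correlation.

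Interferon and antigen presentation genes went the other way. Of 21, 10 were lower in zG-like cells and 4 higher, with Ifit1 (-5.04 ± 0.49) and Ifit3 (-3.33 ± 0.38) down and Ifi27 (0.59 ± 0.09) and Psmb8 (0.45 ± 0.12) up. The camera adjusted p was 0.000753, and adjusted p = 0.257 with an estimated correlation. Ifit1 was low throughout, at 0.250 normalised CPM in zG-like cells and 5.10 in cluster 2, and its level in cluster 9 rested on library 1 (51.9 against 4.46 in library 2). The list also passed camera against cluster 2 alone (7.82e-05) and cluster 9 alone (0.0248), and adjusted p = 0.16 and 0.271 with an estimated correlation.

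The remaining 9 lists did not pass camera. Steroidogenic enzymes and cofactors split into 6 higher and 5 lower of 17 (camera adjusted p 0.363), with Fdx1, the electron donor of mitochondrial steroid enzymes, higher (1.14 ± 0.15) and Cyb5r3 lower (-1.20 ± 0.08). Fdx1 was low in cluster 2, at 1128 against 3963 normalised CPM. Cholesterol uptake, storage and efflux had 9 of 17 higher and 3 lower (0.508). Plin1, a lipid droplet coat protein, was higher (1.64 ± 0.15), as was Osbpl1a (0.84 ± 0.16). The cholesterol exporter Abca1 (-2.74 ± 0.11) and Lrp1 (-1.13 ± 0.11) were lower. The ACTH and cAMP list had 9 of 21 higher and 3 lower (0.218), with Crem (1.34 ± 0.19) up and Pde8b (-0.94 ± 0.18) and Adcy9 (-0.71 ± 0.13) down. Nuclear receptors and transcription factors had 8 of 29 higher and 6 lower (0.687), including Zfpm2 (1.28 ± 0.26), Nr1h3 (-2.51 ± 0.36) and Vdr (-2.50 ± 0.47). Immediate early genes had 11 of 21 higher and 3 lower (0.158). Against cluster 2 alone 6 were higher and 10 lower (median -0.31, camera adjusted p 0.103), and against cluster 9 alone 11 were higher and 2 lower, which passed (0.0449, and adjusted p = 0.271 with an estimated correlation). Fosb had no UMI in cluster 9 and, in zG-like cells, 4.18 normalised CPM in library 1, under that library's floor of 3 UMIs in cluster 9, and 31.8 in library 2. It was higher in cluster 2 than in zG-like cells (0.69 ± 0.18), and Fosl2 (-3.64 ± 0.11) and Jun (-1.46 ± 0.08) were lower in zG-like cells. Heat shock and unfolded protein genes had 3 of 23 higher, among them Hspe1 (1.14 ± 0.11) and Hspd1 (0.61 ± 0.11), and 5 lower, among them Calr (-0.50 ± 0.07) and Hspa5 (-0.43 ± 0.09) (0.57). Antioxidant and glutathione genes had 11 of 30 higher and 10 lower (0.367), with Txn2 (1.35 ± 0.09) and Gsta4 (1.04 ± 0.10) up and Gpx3 (-3.53 ± 0.37) and Mt2 (-2.79 ± 0.14) down. Gsta4 and Mt2 have close paralogs that may share reads. Basement membrane and matrix genes had 8 of 19 higher and 4 lower (0.518), with Col18a1 (2.95 ± 0.21) up and Col4a5 (-1.28 ± 0.38) and Lamb2 (-0.85 ± 0.14) down. Of 28 cell cycle genes, 2 were higher and none lower (0.565). Mcm2 was up by 0.95 ± 0.19, and Hells, with 3 UMIs in cluster 9, stood at 3.76 times that level (counting interval 1.29 to 18.2). In library 1 and library 2 alone, log2 differences were 1.00 and 1.85 for Crem, -3.91 and -3.13 for Fosl2, -0.46 and -1.52 for Col4a5, -1.13 and -0.44 for Lamb2, and 0.58 and 1.58 for Mcm2.

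Counts adjusted over the list alone were the same for 12 of the 17 lists. They came to 16 higher for the WNT list, 19 for the angiotensin list, 30 for oxidative phosphorylation, 13 for ribosomal proteins and 1 for the cell cycle. Median and camera direction differed in sign for the heat shock list (median 0.05, camera lower) and the antioxidant list (median 0.10, mean -0.19, camera lower), and with RLE size factors the heat shock median was -0.03. The nuclear receptor list had a median of -0.001 and a mean of 0.04. With unseen genes at the floor, the medians of the matrix list and the cell cycle list turned from 0.62 to -0.06 and from 0.46 to -0.76. No list passed with an estimated correlation. Against cluster 2 alone, Gpx3 was higher in zG-like cells (1.82 ± 0.37, edgeR adjusted p 0.000168). Cabp1 (0.26), Vdr (0.14), Sdhb (0.12), Rplp0 (0.064) and Osbpl1a (-0.17) had the opposite sign there but did not pass, so their calls lay with cluster 9. Another 13 of the 84 named genes were weaker against cluster 2 alone, keeping their sign but not their side of the threshold. Values given for single genes therefore need not hold against both zF-like clusters.

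The comparison of the zF-like clusters with each other asked how uniform that class was, and it was not. Cluster 9 had 980 normalised CPM of Gpx3, an extracellular glutathione peroxidase, against 0.559 in cluster 2 (log2 difference 10.69 ± 0.21, n = 2 libraries, edgeR adjusted p 5.95e-34). Cabp1 (9.19 ± 0.33), Aldh1a1 (8.53 ± 0.14) and Lgals3 (7.98 ± 0.26) were the next 3, with Lgals3 at 7.48 in library 1 alone and 8.67 in library 2 alone. Lhfpl2, Cxcl10, Bex4 and Fos had no UMI in cluster 9. Lhfpl2 was at least 14.4-fold higher in cluster 2 (at least 6.92-fold and 7.41-fold with library 1 or 2 alone) and Bex4 at least 10.8-fold (7.39 and 3.56). The bounds for Cxcl10 and Fos rested on library 2, at least 11.4-fold and 7.48-fold there against 1.10 and 1.66 in library 1. The Cxcl10 signal also came from few cells, with 119 UMIs in 5 cells of library 1 and 715 in 6 cells of library 2. Cluster 9 was higher than cluster 2 in Hsd3b1 (1.10 ± 0.21), Star (0.73 ± 0.19) and Cyp11a1 (0.56 ± 0.17), and lower in Mc2r (-3.40 ± 0.23), Cyp21a1 (-2.04 ± 0.27) and Axin2 (-1.27 ± 0.23).

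edgeR called 708 genes higher and 744 lower in cluster 9, and the split was 858 higher and 581 lower with RLE size factors, which raised the median of all genes by 0.11 on the log2 scale. Tests of the gene lists in this comparison were added after the data were seen. Camera called 7 of the 17. Hedgehog and FGF genes had 9 of 18 lower and 1 higher in cluster 9 (adjusted p 0.000121, and adjusted p = 0.0852 with an estimated correlation), and immediate early genes 10 of 21 lower and 2 higher (0.00312, and adjusted p = 0.127 with an estimated correlation). Angiotensin, potassium and calcium genes had 15 of 34 lower and 4 higher (0.0103, and adjusted p = 0.0852 with an estimated correlation), and WNT genes 10 of 28 lower and 3 higher (0.0205, and adjusted p = 0.232 with an estimated correlation). Steroidogenic genes had 9 of 17 higher and 3 lower (0.0114, and adjusted p = 0.127 with an estimated correlation). Oxidative phosphorylation had 6 of 42 higher and 1 lower, and ribosomal proteins 4 of 48 higher and none lower (0.0114 and 0.00312, and adjusted p = 0.462 and 0.66 with an estimated correlation). Cluster 9 rests on 24 cells of library 1 and 27 of library 2. Without the library term 775 genes were called, and with cells thinned to 5000 UMIs 671.

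Cycling cells were counted per class, after clustering had set apart clusters 5 and 8, which were led by cell cycle genes. Low shares in the named classes therefore do not show which states divide. With each cell thinned to 5000 UMIs, 6.06% of cortical cells in library 1 (exact 95% interval 5.37 to 6.81) and 8.11% in library 2 (6.82 to 9.56) had UMIs of at least 3 cell cycle genes. The zG-like class reached 2.98% and 6.25%, and the zF-like class 4.18% and 5.15%. Immune-gene clusters, the background class, reached 4.76% and 3.57% over 42 and 28 cells, so the shares in both named classes could not be told from background at this depth. Median depths before thinning were 18624 and 16161 UMIs in cortical cells and 8377 and 7134 in the immune-gene clusters. Cluster 8 stood far above these values at 98.6% and 94.7%, as did cluster 5 at 47.2% and 42.6%. Without thinning the cortical shares were 41.2% and 36.8%. Cluster 5 took 2.35% and 2.94% of kept cells and cluster 8 took 1.58% and 1.02%. Clusters 5 and 8 had 98.7 and 92.5 CPM of Cyp11b1, against 947 in cluster 2, 124 in cluster 0 and 185 in cluster 1. Their Cyp11b2, at 31.0 and 40.4 CPM, lay between cluster 2 (9.99) and clusters 0 (129) and 1 (65.1).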

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

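Both tests of explanations given here were chosen after the result was seen.

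A signal outside the gene comparisons was eGFP, the product of the recombined reporter, in clusters led by immune genes. Macrophage-like cells had 2441 CPM of eGFP in library 1 and 3437 in library 2, lymphocyte-like cells 2592 and 2734, and the unnamed immune clusters 2927 and 3768, all above the limit that a count of 0 allows.

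Free RNA or doublets would bring eGFP and Star in the ratio of cortical cells. The ratio in the immune-gene clusters was 13.9 times the cortical one in library 1 (interval 11.3 to 17.4) and 19.2 times in library 2 (14.6 to 25.6), which argues against that source as the main one. Macrophage-like cells came nearest, at 5.35 and 7.30 times. Whether the immune cells may carry a recombined reporter cannot be told apart from reads of an unrecombined one, since TdTomato had 2 UMIs in all kept cells and no unrecombined cells serve as a reference. No biological explanation was tested, as the design holds 1 group.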

How the results depend on the processing

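Leiden seeds 2 and 3, single zF-like clusters, the fit without clusters 3 and 6, and all settings of the comparisons of cluster 0 with 1 and of cycling with zG-like cells were chosen after the data were seen. The cause was not tested for any change given here, except where a setting leaves fewer UMIs or cells.

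For zG-like against zF-like cells, 2355 genes were called, 1237 without the library term and 1247 with thinned cells, which hold fewer UMIs (5079 genes tested). The other settings gave 1991 to 2572. Between the zF-like clusters the count of 1452 went to 775 and 671 under the same settings, and otherwise lay between 1373 and 1567. The 1947 genes between clusters 0 and 1 became 1122 with DESeq2 and 0 in edgeR without the library term, where 443 had an unadjusted p under 0.05. The 2160 genes of the cycling clusters became 788 without that term. Thinned cells gave no value there, since cluster 8 kept too few cells in library 2. Of 17 lists, camera called 8, against 0 with an estimated correlation, 5 with cluster 2 alone and 4 with cluster 9 alone. Fry also called 4 lists that camera did not, all as higher in zG-like cells. They were the ACTH and cAMP list (fry adjusted p 0.00431), immediate early genes (0.00431), matrix (0.00659) and cell cycle (0.00974). The medians of the matrix and cell cycle lists changed sign with unseen genes at the floor. Fry did not call 2 lists that camera did, mitochondrial-encoded (0.104) and ribosomal (0.125). The zF-like share, 22.7% on average, was 30.9% with at least 1500 genes per cell. With Leiden seed 2 it was 24.4% in library 1 and 28.9% in library 2, against 19.4% and 25.9% in the main setting. Cycling cells, 7.09% on average, were 21.5% with at least 2 genes, 2.46% with at least 5 and 39.0% unthinned.

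For the genes named in zG-like against zF-like cells, 84 of 1660 values were weaker, 6 stronger and 15 reversed. Each library alone allows no test. There 35 of 84 genes moved by more than the spread between libraries without replicate 1 and 30 without replicate 2. Single-library values are shrunken by a prior count of 2 and the fitted ones are not. A gene can thus count as moved where its libraries agree, as for Cd24a, at 4.76 and 4.64 against a fitted 6.73. Counts of moved genes in this part therefore do not measure disagreement between libraries. The remaining 1490 values kept their direction, and their side of the threshold where a test was possible. With class sums, log2 values changed sign to -0.21 for Nr0b1, -0.14 for Osbpl1a, -0.11 for Mc2r, -0.48 for Fosb and -0.27 for Cyp21a1, because cluster 2 holds most zF-like cells. Of these only Fosb passed (adjusted p 0.00299). With cluster 2 alone they were -0.19, -0.17, -0.10, -0.69 and -0.25 for the same genes, and 0.26 for Cabp1, 0.14 for Vdr, 1.82 for Gpx3, 0.12 for Sdhb and 0.064 for Rplp0, of which Fosb (0.00209) and Gpx3 (0.000168) passed. Genes without a UMI in the 51 cells of cluster 9 have only bounds. For other named results, 3 of 63 values between the zF-like clusters and 12 of 96 between clusters 0 and 1 were weaker, and none of 84 in the cycling clusters. Without replicate 1 or 2, 6 and 7 of 8 genes moved between the zF-like clusters, 4 and 1 of 12 between clusters 0 and 1, and 7 and 6 of 12 in the cycling clusters. Single lists stayed on their side in 76 of 102 cases, with 21 weaker and 5 stronger.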

Other observations

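All comparisons in this part, and all tests but that of whether clustering parted like cells by library, were chosen after the result was seen.

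Cluster 2, the larger zF-like cluster, was compared with zG-like cells alone. Hhex, a homeobox factor, rose by 2.19 ± 0.12 on the log2 scale (n = 2 libraries), the cholesterol exporter Abca1 by 2.18 ± 0.10 and Filip1l by 2.07 ± 0.13. Gulo, the last enzyme of vitamin C synthesis, changed by -3.33 ± 0.19, Ppp2r2b by -2.94 ± 0.14 and Tmem158 by -2.85 ± 0.15 (-2.49 and -3.45 in single libraries). Lower in cluster 2 were 20 of 24 cholesterol synthesis genes, 38 of 42 oxidative phosphorylation genes, 11 of 13 mitochondrial-encoded and 16 of 48 ribosomal protein genes. Camera gave adjusted p-values of 2.61e-09, 9.03e-16, 3.78e-07 and 1.51e-11, and adjusted p = 0.16, 0.0653, 0.537 and 0.537 with an estimated correlation. Of 21 interferon genes, 13 were higher and 4 lower (camera adjusted p 7.82e-05, and adjusted p = 0.16 with an estimated correlation). Malat1 (0.82 ± 0.29) and Neat1 (1.21 ± 0.12) were higher in cluster 2. edgeR called 936 genes higher and 1226 lower.

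Cycling cells (clusters 5 and 8) had lower levels than zG-like cells in steroidogenic genes, but also in other lists. Among these was cholesterol uptake, storage and efflux, with 9 of 17 genes lower and none higher (camera adjusted p 0.00144, and adjusted p = 0.143 with an estimated correlation). Fdx1 stood at 1115 against 3963 normalised CPM (log2 -1.97 ± 0.16, n = 2 libraries, -1.46 in library 1 alone and -2.63 in library 2 alone) and Star was lower by a log2 of -1.03. Of 17 steroidogenic genes 10 were lower and 2 higher, of 24 cholesterol synthesis genes 16 lower and 1 higher (camera adjusted p 0.00144 and 0.000517, and adjusted p = 0.0957 and 0.265 with an estimated correlation). Oxidative phosphorylation (26 of 42 lower, 1 higher) and ribosomal proteins (23 of 48 lower) also moved (0.000517 and 2.86e-06, and adjusted p = 0.26 and 0.521 with an estimated correlation), and Malat1 was lower (-0.66 ± 0.24, edgeR adjusted p 0.028). All 28 cell cycle genes were higher, a list that also describes how the clusters were recognised, with Mki67 at 409 against 0.240 normalised CPM. Some of the lower levels were also seen in cluster 2, where Fdx1 stood at 1128 normalised CPM. There 20 of 24 cholesterol synthesis, 38 of 42 oxidative phosphorylation and 16 of 48 ribosomal protein genes were lower than in zG-like cells, and none higher. The steroidogenic list did not pass for cluster 2, with 5 of 17 lower and 3 higher (camera adjusted p 0.624). For the cycling clusters, edgeR called 960 genes higher and 1200 lower, and with RLE size factors 1075 and 917.

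The zG-like clusters differed mostly by small steps, with 12 genes higher and 19 lower by at least 2-fold in cluster 0. Id3 (-1.45 ± 0.17, n = 2 libraries) and Id1 (-1.18 ± 0.14), inhibitors of differentiation factors, were lower in cluster 0, and the nuclear RNA Kcnq1ot1 was higher (0.96 ± 0.14, with 1.42 in library 1 alone and 0.52 in library 2 alone). Lower in cluster 0 were 36 of 42 oxidative phosphorylation genes and 19 of 30 antioxidant genes. Their camera adjusted p-values were 8.24e-14 and 2.06e-07, and adjusted p = 0.0491 and 0.00714 with an estimated correlation. Ribosomal protein genes (32 of 48) and interferon genes (11 of 21) were lower too (4.59e-20 and 0.00275, and adjusted p = 0.205 and 0.175 with an estimated correlation). Malat1 stood at 27110 against 11870 normalised CPM in library 1 and 24780 against 24290 in library 2 (0.60 ± 0.34, edgeR adjusted p 0.181), and Neat1 was higher in cluster 0 (0.57 ± 0.16, edgeR adjusted p 0.00651). edgeR called 622 genes higher and 1325 lower, with RLE size factors 811 and 1104, and without clusters 3 and 6 in the fit 1027 and 1222. Without the library term it called 0, with 443 at an unadjusted p under 0.05, and DESeq2 with the term called 1122.

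Libraries differed within zG-like cells. Library 2 had more Fosb (36.2 against 4.13 CPM), Fos (58.2 against 12.3), Kcnq1ot1 (648 against 195) and Hmgcs1 (156 against 53.5), and library 1 had more Rps29 (3612 against 1447) and Gm42418 (5031 against 915).

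Cluster 3 had few UMIs per cell and little Malat1, a nuclear RNA. Depth alone is argued against, since on thinned cells nuclear RNAs differed from cluster 2 by a median log2 of -4.22 in library 1 and -4.66 in library 2. Erythrocyte RNA is argued against too, since without 7 of its 553 cells, which were rich in haemoglobin, Malat1 still differed by -6.27. A candidate explanation is cytoplasm that lost its nucleus, with a median of -4.06 and -4.54 for nuclear RNAs other than Malat1 and 0.58 and 0.59 for 48 ribosomal protein genes, although the sort on a DNA dye should remove such particles. No biological explanation was tested.

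Cluster 4 lay almost only in library 1. Nr4a1 stood at 838 against 60.2 CPM in zG-like cells of that library, Nr4a2 at 674 against 37.2 and Sik1 at 73.8 against 2.50. Whether the clustering parted like cells by library could not be told. The share of cortical cells with at least 3 of 5 such genes was 11.3% in library 2 and 8.33% in library 1, a ratio of 1.36. This ratio met the rule set beforehand for clustering that parted like cells, but the rule cannot decide here. Outside cluster 4 the share was 11.1% in library 2 and 4.40% in library 1. The 5 genes were higher on average in zG-like cells of library 2, with Nr4a1 at 159 CPM and Nr4a2 at 93.5. Such a rise can lift the share in library 2 without cells like those of cluster 4. A stress response to dissociation cannot be told apart, because 2 of 8 stress genes, Fosb (3.62) and Atf3 (3.82), rose by a log2 near the median of 3.80 for Nr4a1, Nr4a2 and Nr4a3, while the median of the 8 was 0.78. No biological explanation was tested.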
